A study of Mus musculus with 32 samples.

How the data were processed

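RNA was measured in 32 libraries of 3T3-L1 adipocytes, 4 in each of 8 groups: DMSO vehicle, SCO, CAP7 or ROSI, each without and with TNF-alpha for 24 h. The labels name the 4 libraries of a group biological replicates and give no batch or day. Per the labels' protocols, the libraries were made with the QuantSeq 3' mRNA method, which yields reads near the 3' end of a transcript. The deposited table holds raw counts per Ensembl gene, 1 column per library, with no normalization. Per the submitters' processing notes, the tools were cutadapt 4.9, STAR 2.7.11b, HTSeq 2.0.5, R 4.4.1 and limma 3.60.6 with the genome build GRCm39. The handling of reads that map to several genes is not stated, so genes with near-identical copies are uncertain. No coordinates are given, because the annotation at hand is of another build and served for gene symbols only.

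Of 57186 genes listed, 28862 had a count, and 14428 passed edgeR's filterByExpr by group and were tested, 13983 of them with a symbol. Library totals ran from 11.31 to 37.68 M counts (M, counts in 1e6), with a median of 20.87. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F test, 1 mean per group, all 32 libraries in 1 fit, 24 residual degrees of freedom, common biological coefficient of variation 0.1116). Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison were called. The 16 comparisons were TNF against none in vehicle-treated cells, each compound against DMSO without and with TNF, each pair of compounds without and with TNF, and each compound's interaction with TNF. These comparisons and their tests, the gene lists, most alternatives and the rule for named genes were chosen before the data were examined. Tests and alternatives chosen later are named as such below. Intervals of 95% come from the same fit.

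There were 21 gene lists with 437 tested genes, written from general knowledge: PPARγ targets, adipocyte identity, de novo lipogenesis, triglyceride synthesis, lipolysis and lipid droplet, NF-κB and TNF response, acute phase and complement, interferon response, extracellular matrix, fatty acid oxidation, respiratory chain and TCA cycle, brown and beige adipocyte, insulin signalling and glucose uptake, NRF2 antioxidant, aryl hydrocarbon receptor targets, cholesterol synthesis, unfolded protein and amino acid stress, preadipocyte and fibroblast markers, cell cycle, macrophage and leukocyte markers, and endothelial and mural markers. Each was tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. List p values were adjusted over the 21 lists of a comparison. Some lists share genes, so their counts are not separate results. Adipoq, Fabp4, Plin1, Cd36, Lpl and Cidec are both PPARγ targets and adipocyte identity genes here. Pdk4, Cpt1b, Cpt2, Ehhadh, Pex11a and Acaa1b are in the lists of PPARγ targets and fatty acid oxidation, and the lipolysis and lipid droplet list also shares genes with the PPARγ targets.

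Genes were named by rule. In the 7 comparisons with a control, these were the 8 largest increases and decreases among called genes with at least 16 CPM in a group and no overlap between groups. For pairs of compounds and interactions the number was 4. Up to 4 members of each described list with the lowest p, and 25 genes chosen in advance, could also be named.

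Compounds measured against the same control share its chance values. Shared calls were therefore set beside the number for independent lists and beside fits with the control libraries split 2 and 2, and correlations and covariances of fold changes also beside 20 simulated draws of unchanged groups. Genes called for ROSI in one state were tested in SCO in the other state, which shares no library. The share of TNF-called genes that moved back was taken again with the libraries with TNF alone split, and with a TNF list from the libraries of the other compounds.

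The methods were tested on simulated counts with 200 genes changed by known folds. For SCO with TNF, edgeR recovered 24%, 70%, 86% and 100% of genes changed 1.25, 1.5, 2 and 4-fold, with 2 false calls, and for the interaction 8%, 46%, 76% and 96%, with 10. The false calls were 1.41% and 8.13% of all calls. All groups were drawn from the mean of TNF alone and only SCO with TNF was changed, so the simulated counts held no other effect. The alternatives were RLE factors, no filter on low counts, a stricter filter (5 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, and fitting only the libraries of the groups compared. Library size alone, leaving out mitochondrial genes and the most abundant unnamed gene, and thinning to the lowest total were added later.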

Results

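3T3-L1 cells, a mouse preadipocyte line, were differentiated into adipocytes and treated for 24 h with DMSO vehicle or with 1 of 3 compounds, each alone or together with TNF-alpha (TNF), a cytokine that makes fat cells inflamed and insulin resistant. SCO is not defined in the labels, and the series title names an Artemisia scoparia extract. Rosiglitazone (ROSI) is an agonist of PPARγ, the nuclear receptor that drives fat cell differentiation. What CAP7 is, and the dose of each treatment, are not given in the sources used here. Gene expression was measured by sequencing the 3' ends of mRNA in 32 libraries, 4 in each of 8 groups, with totals from 11.3 to 37.7 M counts per library (M, counts in 1e6; median 20.9 M). By group the mean totals were 15.6 M for DMSO, 15.03 for SCO, 22.4 for CAP7 and 20.8 for ROSI without TNF, and 23.0, 23.7, 23.8 and 24.2 M with TNF. Libraries with and without TNF separated along the first principal component, which held 53% of the variance, and within each of these 2 states the treatments separated along the second, with 7.88%, where SCO with TNF overlapped CAP7 without TNF. Below, fold changes are log2 values with their standard error (n = 4 against 4), levels are normalized counts per 1e6 counts (CPM) with their SD (n = 4), and rises and falls are those with an edgeR adjusted p under 0.05 among 14428 genes. The balance of higher and lower calls depended on the scaling between libraries: in the 6 comparisons of a compound with its control 49.2% to 62% of the calls were higher, and 27.8% to 44.2% with library sizes alone.

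**Figure D1:**
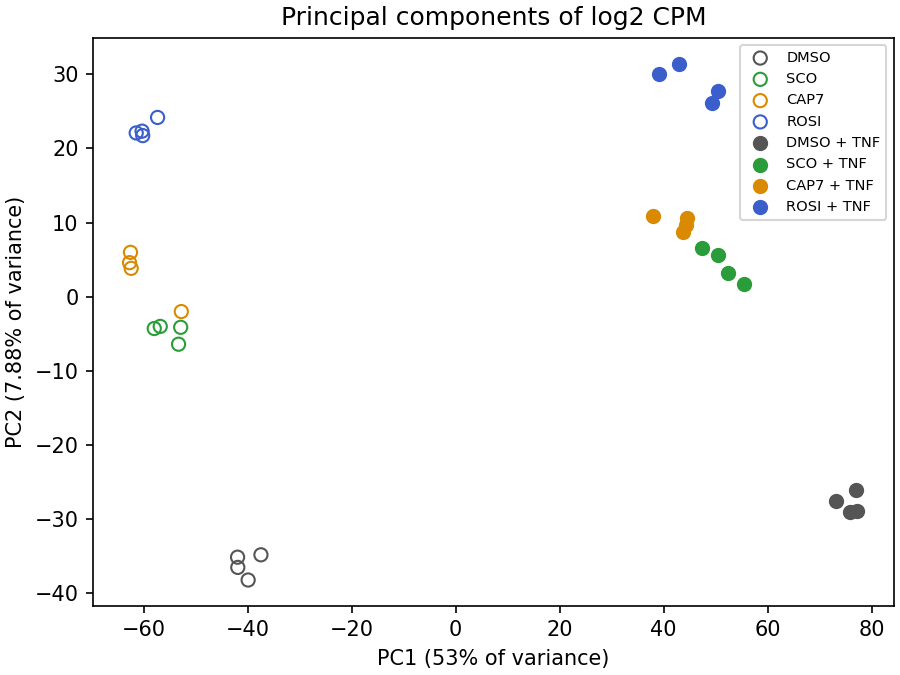
First and second principal component of log2 CPM over the 14428 genes, 1 point per library (n = 4 in each of 8 groups), with filled points for libraries with TNF and open points for those without. The first component, with 53% of the variance, separates libraries by TNF, and along the second, with 7.88%, DMSO lies at one end and ROSI at the other, with SCO and CAP7 between them.

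The first comparison asked what TNF did to adipocytes that received vehicle only. TNF raised inflammatory genes and lowered genes of the mature fat cell. Saa3 (ENSMUSG00000040026), an acute phase protein, rose from 1.99 ± 0.796 to 6422 ± 556 CPM, a log2 change of 11.63 ± 0.22. The chemokines Ccl2 (6.44 ± 0.158) and Ccl5 (9.50 ± 0.32), the matrix protease Mmp3 (7.11 ± 0.188) and Lcn2, an iron-sequestering acute phase protein (5.57 ± 0.147), rose as well. All 38 measured genes of the list for the NF-κB and TNF response rose (38 adjusted over the list alone), among them the inhibitor Nfkbia at 2.96 ± 0.0728 and the chemokine Cxcl1 at 5.52. Of 19 acute phase and complement genes 16 rose and 1 fell (the same counts adjusted over the list alone). All 36 interferon response genes rose, also over the list alone, but as a set they stood apart from other genes only with the preset correlation (camera adjusted p = 5.02e-12, and 0.178 with an estimated correlation). Of 5 measured leukocyte markers 3 rose, among them Cd68 (3.54), with the same count adjusted over the list alone, and this call was lost with an estimated correlation (adjusted p = 0.0884). These markers were at low levels, from 0.376 CPM for Lyz2 to 6.12 CPM for Cd68 with TNF plus SCO.

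Genes of lipid storage and of fat cell identity were among those that fell with TNF. Thrsp, a regulator of lipogenesis, fell by 5.37 ± 0.17, from 335 ± 35.7 to 8.07 ± 1.3 CPM, the beta-3 adrenergic receptor Adrb3 by 5.24 ± 0.144, and Pck1, which makes the glycerol backbone of triglycerides, by 3.78 ± 0.164. Of 19 adipocyte identity genes 18 fell and 1 rose, and of 31 PPARγ targets 26 fell and 3 rose (the same counts adjusted over the list alone). Cidec, a lipid droplet protein, fell by 3.85, the transcription factor Cebpa by 2.80 ± 0.089, the hormone-sensitive lipase Lipe by 2.63 ± 0.0813, the glucose transporter Slc2a4 by 2.44 ± 0.104, Adipoq, which encodes the hormone adiponectin, by 1.78 ± 0.0731 and Pparg itself by 1.42 ± 0.0794. Angptl4, a PPARγ target that inhibits lipoprotein lipase, went the other way (1.96 ± 0.0633). All 33 respiratory chain and TCA cycle genes fell, as did 24 of 26 fatty acid oxidation genes (1 rose), 22 of 24 cholesterol synthesis genes, 14 of 17 lipogenesis genes, 14 of 18 triglyceride synthesis genes (2 rose), 15 of 19 lipolysis and droplet genes (2 rose), 19 of 27 insulin signalling genes (6 rose) and 9 of 13 brown adipocyte genes (3 rose). Adjusted over the list alone these counts were the same, except for 1 lipogenesis gene that then rose. The fall of the brown adipocyte list did not hold with an estimated correlation (adjusted p = 0.0763).

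Of the other lists, preadipocyte and fibroblast markers did not move together, with 7 of 19 higher and 5 lower, Cd44 rising by 3.18 and Dlk1 falling by 0.90. Of 30 cell cycle genes 26 rose (27 adjusted over the list alone), with Mcm3 at 1.45 and Top2a at 1.12, but this set was not apart from other genes with an estimated correlation (adjusted p = 0.174). Of 36 matrix genes 10 rose and 22 fell (11 and 22 over the list alone), of 31 NRF2 antioxidant genes 12 rose and 10 fell, of 27 genes of the unfolded protein and amino acid stress response 11 rose and 8 fell (12 and 8), of 5 aryl hydrocarbon receptor targets 2 rose and 3 fell, and of 3 vessel markers 2 fell. The vessel markers were at low levels, from 0.524 CPM for Pecam1 to 2.18 CPM for Myh11 with TNF plus SCO. In all, edgeR called 3852 genes higher and 3965 lower, and 2716 of these changed at least 2-fold.

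The next comparisons asked what each compound did to adipocytes without TNF, with ROSI as the reference for PPARγ targets. SCO raised PPARγ targets and lowered matrix, acute phase and cell cycle genes. Pck1 (ENSMUSG00000027513) rose from 48.3 ± 7.09 to 151 ± 8.54 CPM (1.64 ± 0.131), Fabp4, the fat cell fatty acid binding protein, by 1.24 ± 0.102, the fatty acid transporter Cd36 by 0.97 ± 0.0638, Angptl4 by 1.14 ± 0.0623 and Pdk4, which turns cells from glucose to fat oxidation, by 1.20 ± 0.147. Of 31 PPARγ targets 24 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.74. Arxes2 (1.74 ± 0.088), whose copy Arxes1 can share its reads, Scd3 (1.71 ± 0.239), a close relative of the desaturases Scd1 and Scd2, and Hcar2 (1.42 ± 0.117), an antilipolytic receptor, were also among the largest rises. Hmox1, the heme oxygenase induced by oxidative stress, rose by 1.64 ± 0.207, and 20 of 31 NRF2 antioxidant genes rose with none lower (21 over the list alone), among them Cbr3 at 1.10 and Pgd at 0.67. Nqo1 did not pass the test (0.12 ± 0.118). Fat oxidation genes (20 of 26) and respiratory chain genes (26 of 33) rose, 21 and 30 over the list alone, while Pparg fell by 0.50 ± 0.0781 and Adipoq did not pass the test (-0.12 ± 0.071, 95% interval -0.26 to 0.03).

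The decreases with SCO included the matrix protein gene Tgfbi (-1.62 ± 0.194) and the contractile gene Acta2 (-1.34 ± 0.162). Of 36 matrix genes 26 fell and 1 rose (the same over the list alone), with Col3a1 at -0.72, and 14 of 19 acute phase genes (15), with Hp at -1.20. Of 19 preadipocyte and fibroblast markers 13 fell and none rose (14 over the list alone), and of 30 cell cycle genes 19 fell (21), with Cdk1 at -0.55. Ccl2 fell by 1.30 ± 0.154. In all, edgeR called 1484 genes higher and 1297 lower, with 272 of them changed at least 2-fold.

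CAP7 without TNF raised PPARγ targets and lowered cell cycle genes. Pck1 rose by 2.00 ± 0.131, Fabp4 by 0.96 ± 0.101 and Angptl4 by 1.13 ± 0.0622, and 27 of 31 PPARγ targets rose with 1 lower (28 and 2 adjusted over the list alone; median 0.60). Hmox1 rose from 113 ± 13.8 to 561 ± 76.9 CPM (2.31 ± 0.21), and 17 NRF2 genes rose with 3 lower (19 and 3), Nqo1 among the latter at -0.74 ± 0.12. The oxidoreductase gene Ero1l (1.76 ± 0.187) and the transcription factor Fosl1 (1.66 ± 0.108) were among the largest rises, and 14 of 27 stress genes rose with 2 lower (also over the list alone), such as Asns at 0.79 and Atf4 at 0.67. Of 33 respiratory chain genes 32 rose (32) and of 26 fat oxidation genes 21 (21), while 25 of 36 matrix genes fell with 3 higher (25 and 3) and 14 of 19 acute phase genes fell (14). Cell cycle genes fell in 24 of 30 cases (27, with 1 higher, over the list alone), with Rrm2 at -1.24 and Mcm6 at -1.12, and 16 of 19 preadipocyte and fibroblast markers fell with 1 higher (16 and 1). Igfals (-2.31 ± 0.11), Ly6c1 (-2.10 ± 0.148), Ccl2 (-1.96 ± 0.157) and the chemokine Ccl6 (-1.88 ± 0.115) fell most. The call counts were 2200 higher and 2170 lower, 609 of them at least 2-fold.

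ROSI without TNF gave the largest changes. Pck1 rose to 364 ± 22.8 CPM (2.91 ± 0.135), Arxes2 by 2.68 ± 0.0905, the lipid droplet protein Plin2 by 2.10 ± 0.0776, Angptl4 by 1.93 ± 0.0633 and Fabp4 by 1.51 ± 0.103. Acaa1b, a peroxisomal thiolase, rose from 2.03 ± 1.1 to 24.0 ± 2.51 CPM (3.56 ± 0.256). Of 31 PPARγ targets 28 rose (28 adjusted over the list alone), with a median of 1.29, of 26 fat oxidation genes 24 (24) and of 33 respiratory chain genes 32 (32). Pparg fell by 1.13 ± 0.0789. NRF2 genes went both ways, with 13 higher and 6 lower (14 and 7 over the list alone), Nqo1 at -1.44 ± 0.127 and Gstm1 at -1.18, and of 30 cell cycle genes 7 rose and 3 fell (6 and 3). Acute phase genes (14 of 19, also over the list alone), matrix genes (25 of 36 lower and 4 higher, 27 and 4 over the list alone) and preadipocyte and fibroblast markers (15 of 19 lower and 1 higher, 15 and 1) fell, the last not as a set with an estimated correlation (adjusted p = 0.0887). The cytochrome P450 gene Cyp2f2 (-2.98 ± 0.146), Igfals (-2.96 ± 0.115) and the synaptic gene Syn2 (-2.61 ± 0.15) fell most. The calls numbered 2658 higher and 2741 lower, 972 of them at least 2-fold.

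**Figure D2:**
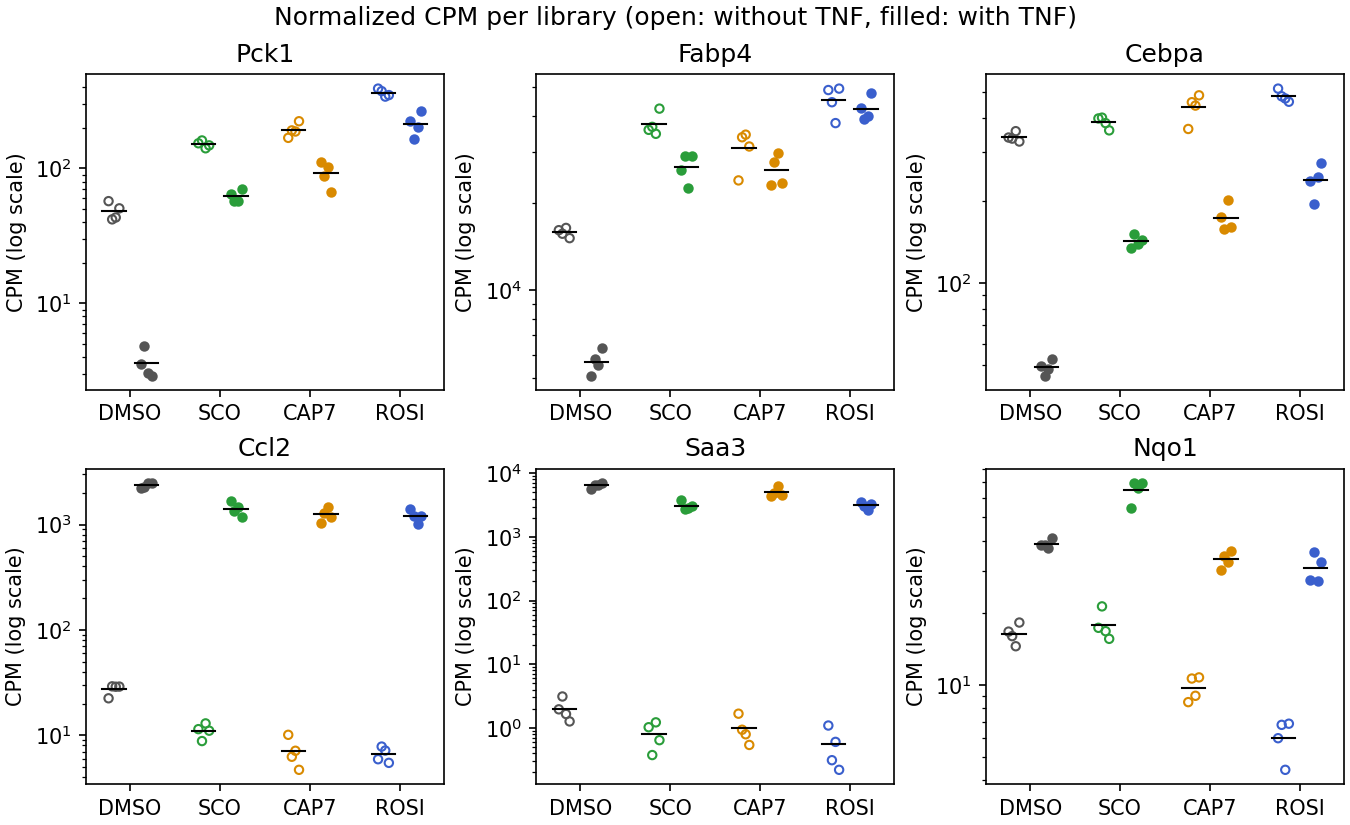
Normalized CPM (log scale) of Pck1, Fabp4, Cebpa, Ccl2, Saa3 and Nqo1 in each of the 32 libraries, by treatment, with open points without TNF, filled points with TNF and bars at the mean of each group (n = 4). Pck1 falls from 48.3 to 3.59 CPM with TNF in vehicle-treated cells and lies at 62.4, 92.0 and 215 CPM with TNF plus SCO, CAP7 and ROSI.

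The comparisons with TNF asked what each compound did to inflamed adipocytes. With SCO, 1484 of the 3965 genes that TNF had lowered were higher. Pck1 rose from 3.59 ± 0.877 to 62.4 ± 6.61 CPM (4.14 ± 0.163), above its 48.3 CPM in untreated cells, Cidec by 2.59 ± 0.0806, Fabp4 by 2.23 ± 0.105, Lipe by 1.94 ± 0.0794, Cebpa by 1.53 ± 0.086 and Slc2a4 by 1.13 ± 0.101. Of 31 PPARγ targets 28 rose (30 adjusted over the list alone; median 1.30), of 19 adipocyte identity genes 15 (16), of 26 fat oxidation genes 24 (24), of 33 respiratory chain genes 32 (32), of 17 lipogenesis genes 15 with 1 lower (16 and 1) and of 31 NRF2 genes 19 (22). Nqo1 rose by 0.75 ± 0.104. Pparg did not pass the test (-0.05 ± 0.0783).

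Inflammatory genes fell in part with SCO. Ccl5 fell from 457 ± 57.5 to 122 ± 41 CPM (-1.90 ± 0.185), Cxcl10 by 1.67 ± 0.284, Il6 by 1.91 ± 0.367, Saa3 by 1.05 ± 0.13, Ccl2 by 0.74 ± 0.122 and Lcn2 by 0.56 ± 0.1, whereas Nfkbia did not pass the test (-0.06 ± 0.0673, 95% interval -0.19 to 0.08). Of 38 NF-κB and TNF response genes 20 fell and 1 rose (23 and 1 adjusted over the list alone), and of 19 acute phase genes 13 fell and 2 rose (16 and 2). The antiviral gene Rsad2 was among the largest decreases (-1.68 ± 0.427), a call that DESeq2 did not make (-1.69, adjusted p = 0.187), and 19 of 36 interferon response genes fell with none higher (24 over the list alone). As a set these passed with the preset correlation (camera adjusted p = 1.18e-06), not with an estimated one (adjusted p = 0.322). Preadipocyte and fibroblast markers fell in 12 of 19 cases (12), not as a set with an estimated correlation (adjusted p = 0.0647). The calls numbered 1907 higher and 1167 lower, 465 of them at least 2-fold.

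With CAP7, Pck1 rose to 92.0 ± 19.7 CPM (4.70 ± 0.164), Cidec by 3.01 ± 0.0819, Fabp4 by 2.19 ± 0.105, Lipe by 2.12 ± 0.0798, Cebpa by 1.82 ± 0.0865 and Slc2a4 by 1.63 ± 0.102, and Thrsp, by 2.48. Pparg rose by 0.29 ± 0.0782, and by 0.19 with library sizes alone, where the call was lost (adjusted p = 0.0561). Of 31 PPARγ targets 30 rose (30 adjusted over the list alone; median 1.40), of 19 adipocyte identity genes 16 (16) and of 33 respiratory chain genes all 33. Of 38 NF-κB genes 21 fell and 1 rose (23 and 1), not as a set with an estimated correlation (adjusted p = 0.0511), and Ccl5 fell by 1.64 ± 0.183, Il6 by 1.53 ± 0.359 and Ccl2 by 0.93 ± 0.123. Lcn2 rose by 0.46 ± 0.0991. Saa3 fell by 0.34 ± 0.129, a call lost with DESeq2 and without replicate 2, 3 or 4 of TNF alone or replicate 1, 2 or 4 of TNF plus CAP7, where it lay between -0.346 and -0.284. Acute phase genes were mixed, with 5 of 19 higher and 11 lower (the same over the list alone; adjusted p = 0.295 with an estimated correlation), and 2 of 36 interferon genes rose and 3 fell (2 and 1 over the list alone). Cell cycle genes fell in 23 of 30 cases (26), not as a set with an estimated correlation (adjusted p = 0.0694). Preadipocyte and fibroblast markers fell in 13 of 19 cases (14; adjusted p = 0.0758 with an estimated correlation). Wfdc17 (-2.13 ± 0.184), whose product has a whey acidic protein domain, and the tubulin gene Tubb2b (-1.83 ± 0.216) fell most. There were 2593 higher and 2053 lower calls, 761 at least 2-fold.

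With ROSI, Pck1 rose to 215 ± 42.4 CPM (5.93 ± 0.167), Cidec by 3.74 ± 0.0845, Fabp4 by 2.89 ± 0.108, Pdk4 by 2.83 ± 0.15, Lipe by 2.33 ± 0.0804 and Cebpa by 2.27 ± 0.0875. Of 31 PPARγ targets 30 rose (31 adjusted over the list alone; median 2.06), of 19 adipocyte identity genes 16 (16), of 26 fat oxidation genes 25 (25) and of 33 respiratory chain genes all 33. Ccl5 fell by 1.72 ± 0.184, Saa3 by 1.03 ± 0.13, Ccl2 by 0.98 ± 0.123, Lcn2 by 0.31 ± 0.1 and Nfkbia by 0.20 ± 0.0673. The Lcn2 call was lost without replicate 4 of TNF alone (-0.25) or replicate 3 of TNF plus ROSI (-0.26), and that of Nfkbia without replicate 4 of TNF plus ROSI (-0.16). Of 38 NF-κB genes 19 fell and 2 rose (the same over the list alone), not as a set with an estimated correlation (adjusted p = 0.103). The antimicrobial peptide gene Camp (-2.40 ± 0.181), Ccl6 (-2.23 ± 0.123) and Gas6 (-1.77 ± 0.0982), a ligand of receptor kinases that clear dying cells, fell most. NRF2 genes were mixed (8 higher and 6 lower), as were interferon genes (3 higher and 2 lower), both with the same counts over the list alone, and 14 of 19 preadipocyte and fibroblast markers fell (14; adjusted p = 0.167 with an estimated correlation). There were 2828 higher and 2347 lower calls, 1045 at least 2-fold.

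**Figure D3:**
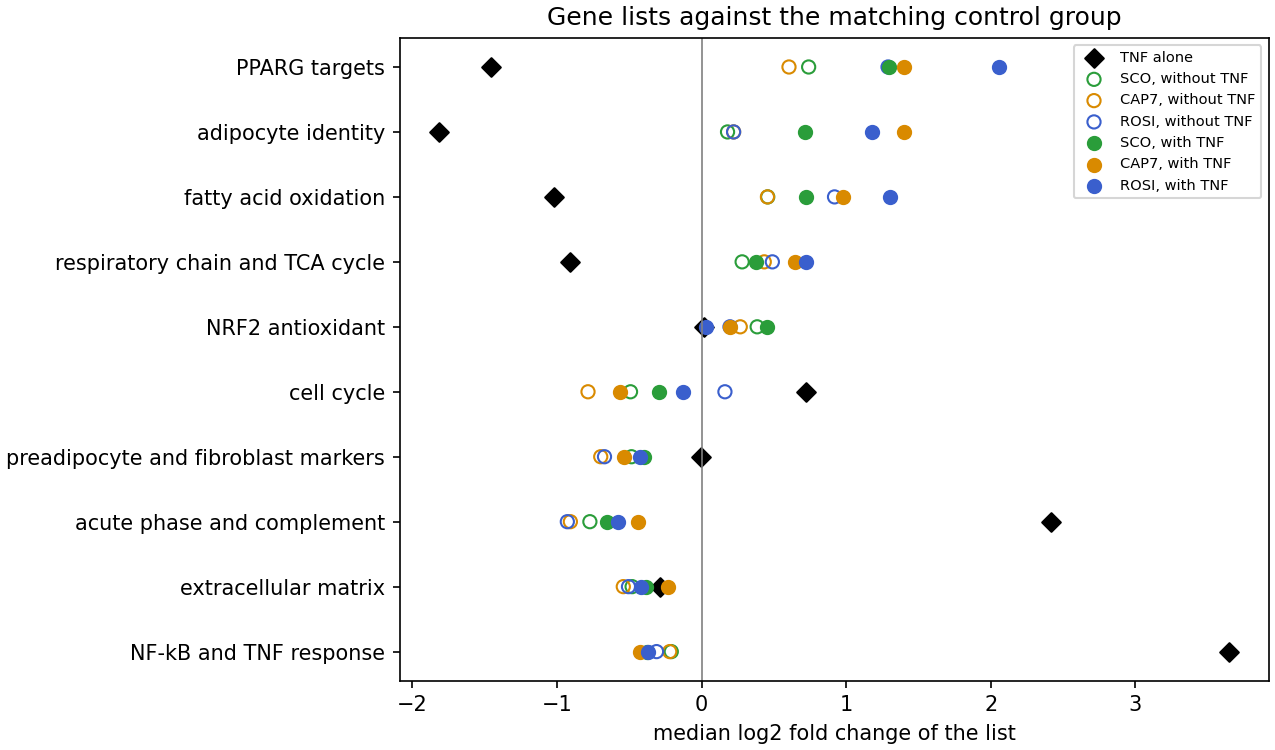
Median log2 fold change of 10 gene lists (rows) in the 7 comparisons with vehicle or with untreated cells, as coloured points on 1 axis, with vertical lines at 0. PPARγ targets lie at -1.46 under TNF alone and at 1.30, 1.40 and 2.06 for SCO, CAP7 and ROSI added to TNF.

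The compounds were then compared with each other, to see where SCO and CAP7 differ from ROSI. Without TNF, PPARγ targets were lower with SCO than with ROSI in 20 of 31 cases and higher in none (23 adjusted over the list alone), with Pck1 at -1.27 ± 0.125, Acaa1b at -1.84 ± 0.22, Plin2 at -0.98 and Angptl4 at -0.78 ± 0.0612. NRF2 genes went the other way, 14 of 31 higher and 4 lower with SCO (18 and 5), led by Nqo1 (1.55 ± 0.127), a quinone reductase, and the glutathione transferase Gstm1 (1.29 ± 0.0763), which has close relatives in its gene family. Cell cycle genes were lower with SCO in 21 of 30 cases (25), with Tk1 at -0.85, Pparg was higher (0.63 ± 0.0785), and Igfals, the acid-labile subunit of the insulin-like growth factor complex, was higher too (1.65 ± 0.117). The calls were 1066 higher with SCO and 1058 lower. With TNF, 25 PPARγ targets were lower with SCO (29) and none higher, with Pck1 at -1.79 ± 0.128, the glycerol kinase gene Gk at -1.60 ± 0.124 and Cebpa at -0.74 ± 0.0831. All 33 respiratory chain genes were lower (33). The epoxide hydrolase Ephx1 (1.32 ± 0.122) and Nqo1 (1.08 ± 0.105) were higher with SCO, as were 15 of 31 NRF2 genes (3 lower; 21 and 5 over the list alone). Saa3 (-0.01 ± 0.129) and Ccl2 (0.24 ± 0.122) did not pass the test, with 95% intervals from -0.28 to 0.25 and from -0.01 to 0.49, though Ccl2 passed with no filter on low counts (adjusted p = 0.00572). The calls were 828 higher and 1246 lower.

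CAP7 also differed from ROSI. Without TNF, 21 of 31 PPARγ targets were lower with CAP7 and 1 higher (23 and 2 adjusted over the list alone), with Acaa1b at -2.15 ± 0.218, and 28 of 30 cell cycle genes were lower (29), with Rrm2 at -1.64 and Top2a at -1.20 ± 0.117. Selenow (ENSMUSG00000041571), which encodes a small selenoprotein, was higher with CAP7 by 1.88 ± 0.0747, and the metallothionein Mt2 by 1.24 ± 0.144. There were 777 genes higher with CAP7 and 904 lower. With TNF, 23 PPARγ targets were lower (25) and 1 higher, with Pdk4 at -1.26 ± 0.137, and the scavenger receptor Olr1 was lower by 1.77 ± 0.108. Selenow (1.60 ± 0.0731), Ephx1 (1.11 ± 0.122) and Lcn2 (0.78 ± 0.1) were higher with CAP7. There were 502 genes higher and 735 lower, 1237 in all, and 791 in all with only the compared libraries fitted.

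SCO was also compared with CAP7. Without TNF, Selenow was lower with SCO than with CAP7 by 1.85 ± 0.0754 (32.03 ± 1.01 against 116 ± 3.46 CPM) and Ero1l by 1.09 ± 0.184, while the chemokine Ccl9 (1.73 ± 0.105), whose relative is Ccl6, and Nqo1 (0.86 ± 0.12) were higher with SCO. PPARγ targets split, with 4 of 31 higher and 7 lower (7 and 8 adjusted over the list alone). The 95% interval of the difference was -0.11 to 0.13 for Angptl4 and -0.16 to 0.15 for Pparg. For Pck1 it was -0.6 to -0.1, below 0, though Pck1 did not pass over all genes (-0.353, edgeR adjusted p = 0.0862). There were 434 genes higher with SCO and 438 lower, 872 in all, and 522 in all without replicate 1 of SCO. With TNF, Selenow was lower with SCO by 1.62 ± 0.073, Lcn2 by 1.02 ± 0.1, Thrsp by 1.18 ± 0.148 and Pck1 by 0.56 ± 0.126, and Nqo1 was higher by 0.96 ± 0.105. PPARγ targets were lower with SCO in 15 of 31 cases (2 higher and 17 lower over the list alone), not as a set with an estimated correlation (adjusted p = 0.0566), and 9 of 30 cell cycle genes were higher (12; adjusted p = 0.0907 with an estimated correlation). There were 596 genes higher and 726 lower, 1322 in all, and 689 without replicate 3 of TNF plus SCO or 723 without replicate 1 of TNF plus CAP7.

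Whether a compound acted differently in the presence of TNF was tested as an interaction, the log2 change with TNF minus that without, which is positive both for a larger rise and for a smaller fall. The log2 increase of Pck1 was larger by 2.50 ± 0.208 for SCO, 2.71 ± 0.207 for CAP7 and 3.02 ± 0.206 for ROSI, that of Lipe by 1.52 ± 0.109, 1.67 ± 0.109 and 1.73 ± 0.109, and that of Cebpa by 1.35 ± 0.118, 1.46 ± 0.118 and 1.77 ± 0.118. The scale matters, as TNF had lowered the starting level. With SCO, Pck1 went from 48.3 to 151 CPM without TNF and from 3.59 to 62.4 CPM with TNF, a smaller rise in CPM. Of 19 adipocyte identity genes 11, 18 and 17 had a positive interaction for SCO, CAP7 and ROSI and none a negative one, while over the list alone 14, 18 and 17 had a positive interaction and 1 a negative one in each case. Angptl4, which TNF raised, was raised less with TNF present, by -0.73 ± 0.0865, -0.43 ± 0.0863 and -1 ± 0.0864. The stress transcription factor Atf3 (-1.58 ± 0.266, -1.62 ± 0.261 and -1.85 ± 0.263) also had a negative interaction. That of Pparg, which fell with each compound without TNF, was positive for all compounds (0.45 ± 0.111, 0.78 ± 0.11 and 0.99 ± 0.111). The interaction was positive for 507 and negative for 163 called genes for SCO, 1480 and 854 for CAP7 and 1458 and 650 for ROSI. Of 36 interferon response genes none passed for SCO, 4 were positive for CAP7 and 3 for ROSI (0, 3 and 1 adjusted over the list alone).

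The series title asks how far SCO and ROSI overlap. Without TNF, 1320 genes rose and 1083 fell with both, 2403 in all, which were 86.4% of the 2781 SCO calls and 44.5% of the 5399 ROSI calls, and 8 genes moved in opposite directions. Lists drawn independently would share 519.8 genes. With the DMSO libraries split 2 and 2 between the compounds, 1426 to 1570 genes were shared, against 251.6 to 281.6 for independent lists. Fewer control libraries also make fewer genes pass, so the drop from 2403 does not measure the effect of shared controls alone. Across genes the fold changes correlated at 0.69, and at 0.325 to 0.395 with the DMSO libraries split. The correlation was 0.50 in simulated unchanged groups that shared 4 DMSO libraries, which were simulated too. The covariance was 0.254, against 0.0549 in the simulated groups. With TNF, 2632 genes were shared, 85.6% of the 3074 SCO calls and 50.9% of the 5175 ROSI calls, with 9 in opposite directions, 563.6 expected of independent lists and 1671 to 1801 with split controls. The correlation was 0.76 (0.49 in simulated groups and 0.474 to 0.53 with split controls) and the covariance 0.286 against 0.0490 in simulated groups. CAP7 shared 3389 genes with ROSI without TNF (817.5 expected of independent lists, 2201 to 2323 with split controls) and 3621 with TNF (842.2, and 2486 to 2557), and 2237 and 2466 with SCO (421.4 and 508.8, and 1303 to 1372 and 1558 to 1698 with split controls).

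To leave shared libraries out, genes called for ROSI without TNF were tested in SCO with TNF. The 2658 genes that ROSI raised had a median of 0.23 in SCO with TNF, with 1205 higher and 34 lower, and the 2741 that ROSI lowered had a median of -0.17, with 123 higher and 764 lower. Both lists stood apart from other genes in the camera test (p = 2.34e-39 and 7.42e-16 with the preset correlation, 2.68e-07 and 1.58e-05 with an estimated one). For CAP7 with TNF the medians were 0.28 and -0.20. In the reverse test, lists from ROSI with TNF had medians of 0.21 and -0.20 in SCO without TNF, and 0.24 and -0.28 in CAP7.

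Of the 7817 genes called for TNF in vehicle-treated cells, 2337 (29.9%) were called with SCO in the opposite direction, here named moved back. Another 235 (3.01%) were called in the same direction as with TNF, here named further away. A gene that moved back can end past its untreated level. Fabp4 lay at 15840 ± 559 CPM in untreated cells, 5692 ± 517 with TNF and 26630 ± 3100 with TNF plus SCO. How many genes did so was not counted. CAP7 moved 45.6% back and ROSI 43.3%, with 3.62% and 6.95% further away. Genes lowered by TNF were raised by SCO in 37.4% of cases and genes raised by TNF were lowered in 22.1%, and the shares were 51.4% and 39.6% for CAP7 and 49.7% and 36.7% for ROSI. Because the same 4 libraries with TNF alone enter both sides, the shares were taken again with those libraries split. This gave 22.1% to 24.9% for SCO, 36.9% to 39.95% for CAP7 and 36.7% to 38.7% for ROSI. Each side then had 2 libraries with TNF alone, which also makes fewer genes pass, so the drop does not measure the effect of sharing alone. With the TNF list taken from libraries of the 2 other compounds, 26.3%, 39.3% and 39.2% of its genes moved back.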

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

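The tests chosen after the results were seen were those of Selenow, the comparison of the interferon with the NF-κB list, the tests of a changed share of adipocytes, and the reassignment of residuals for the interactions.

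Selenow, the small selenoprotein gene, was higher with CAP7 than in every other group. It lay at 116 ± 3.46 CPM (n = 4) with CAP7 against 42.2 ± 3 with vehicle, 32.03 ± 1.01 with SCO and 31.4 ± 1.82 with ROSI, and with TNF at 130 ± 6.44 against 49.0 ± 5.26, 42.4 ± 3.92 and 43.0 ± 2.66. A few libraries do not carry it, since the lowest CAP7 library was 1.97 times the highest of the 24 others, and neither does scaling, since the lowest log2 difference over 6 comparisons and 3 scalings was 1.31. Gpx1 and Selenoh, selenoprotein transcripts known to respond to selenium supply, were higher with CAP7 in all 8 comparisons with SCO and ROSI (median 0.45, and 0.05 for 14 other selenoprotein genes). These 14 genes were not all unchanged. Sephs2 was called lower with CAP7 in each comparison with SCO and ROSI (-0.733 to -0.516). Selenop, Msrb1, Selenot, Selenom, Txnrd1 and Gpx4 were called higher in some of them. Against vehicle Selenoh was higher without and with TNF (0.417 and 0.416) and Gpx1 with TNF (0.779), while Gpx1 without TNF did not pass the test (0.176, adjusted p = 0.0542). Both genes were picked after the values were seen, so this decides nothing about a shared rise of selenium-sensitive transcripts, and what raises Selenow stays open.

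Interferon response genes were lower with SCO than with vehicle under TNF, with a list median of -0.86. The mean log2 CPM of the list differed by -0.83 (exact permutation p = 0.0286, the smallest that 70 arrangements allow for 4 against 4 libraries, and 0.0571 adjusted over 10 such tests). This argues against chance differences between libraries before that adjustment but not after it. No library alone carries it, as the highest median over 8 refits without 1 library was -0.68. A weaker response to TNF in general stays open, because the NF-κB list also fell with SCO (-0.51) and the interferon list is not shown to fall beyond it (-0.32 against vehicle, exact permutation p = 0.114, adjusted 0.127). Compared with CAP7 and ROSI together the interferon list lay lower relative to the NF-κB list (-0.51, exact permutation p = 0.0101, adjusted 0.0571), and against CAP7 and ROSI singly the interferon list differed by -0.47 and -0.66 (exact p = 0.0857 each), so an effect of SCO that the other compounds lack also stays open.

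Adipocyte identity genes fell with TNF and were higher when a compound was added. Genes that went against a lower share of adipocytes in the dish were counted, 6 in all. These were 1 of 19 identity genes that rose and 5 of 19 preadipocyte and fibroblast markers that fell. TNF lowered 3965 of all 14428 genes, so some of 19 markers would be called lower in any case. The count therefore cannot decide whether a lower share accounts for the fall. Most identity genes fell and other such markers rose, so a lower share as part of the fall stays open too. For TNF plus a compound a higher share of adipocytes does not account for the rise as a whole, because the abundant identity genes did not rise alike: of 16 with a mean of at least 100 CPM, the 95% interval left out their median for 12, 13 and 14 with SCO, CAP7 and ROSI, as for Fabp4 (2.23, 2.19 and 2.89) and Cfd (-0.04, 0.12 and -0.02). It could be part of the rise, as 0 genes went the other way with any compound, and this stays open beside an action on the cells present. Counting noise is argued against by the same 16 genes, whose lowest median was 1.17.

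In 7 of 208 groups examined 1 library lay far from the other 3, where chance gives about 1 in 20. This is no more than chance would give. The libraries apart were Nfkbia in vehicle replicate 4 (266 CPM, others 235 to 239), Adipoq in TNF replicate 4 (3190, others 2660 to 2700), Ccl2 in vehicle replicate 1 (22.4, others 28.9 to 29.1) and Cfd in TNF plus ROSI replicate 3 (5180, others 6780 to 6930). Fgf21 did so at a few counts, with 0.168 CPM in vehicle replicate 4, 0.139 in TNF replicate 3 and 0.816 in TNF plus CAP7 replicate 2.

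The effect of each compound differed with TNF in the interaction test, for 670 genes with SCO, 2334 with CAP7 and 2108 with ROSI. Values for SCO, CAP7 and ROSI in turn were 2.50, 2.71 and 3.02 for Pck1, 1.52, 1.67 and 1.73 for Lipe, 1.35, 1.46 and 1.77 for Cebpa, 0.99, 1.23 and 1.38 for Fabp4, 1.01, 1.18 and 1.36 for Plin1, and 1.01, 1.21 and 1.45 for Slc2a4. They were 0.45, 0.78 and 0.99 for Pparg, 0.44, 0.75 and 0.60 for Adipoq, 0.56, 0.71 and 0.87 for Cd36, 0.55, 0.77 and 0.76 for the lipase Pnpla2, 0.63, 0.53 and 1.10 for Nqo1, and -0.73, -0.43 and -1 for Angptl4. With CAP7 and ROSI only, the test passed for Ccl2 (1.04 and 1.08), Retn (0.78 and 1.05), Pdk4 (0.78 and 1.09), Cfd (0.73 and 0.71) and Lpl (0.47 and 0.74), and with ROSI only for Nfkbia (-0.45).

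Other groupings of the same libraries were counted. In each of the 13 comparisons of 2 groups, 1 of 35 splits, the real one, gave as many genes, which argues against chance. It does not exclude chance, as 1 of 35 is the smallest share these splits allow and was not adjusted over the 13 comparisons. The other splits also mix the real groups, which widens the spread within groups and lowers their counts. Fits of the compared libraries alone gave 7862 genes for TNF, 3134, 4538 and 5061 for SCO, CAP7 and ROSI, and 3140, 4667 and 5307 with TNF. For pairs of compounds they gave 1753 (SCO and ROSI), 936 (SCO and CAP7) and 1323 (CAP7 and ROSI), and 1750, 738 and 791 with TNF. The highest other split was 0, except 12 for CAP7 alone, 27 for SCO against ROSI with TNF and 23 for CAP7 against ROSI with TNF. For the interactions 2 of 100 regroupings gave as many genes, the real one included, with 798, 2479 and 2141 genes and 1734, 2757 and 3436 in the highest other. Those highest others left the real groups in 1 state and mixed them in the other. Regrouping breaks the main effect of the compound, so it does not show whether chance can be excluded for the interactions. In a further test both main effects were kept and only the residuals of a model without interaction were reassigned among the 16 libraries. For each compound 1 of 100 assignments, the real one, gave as many genes in limma. The counts were 782, 2449 and 2139 genes against 370, 609 and 1 in the highest other. This argues against chance but does not exclude it, as 1 of 100 is the smallest share these assignments allow.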

How the results depend on the processing

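Library size alone, leaving out mitochondrial genes, thinning and the shuffled replicate numbers were chosen after the data were seen, and the other alternatives before. All counts of calls, shared calls and set results stayed within 1.5 times under RLE factors, both filters, DESeq2, limma-voom and the 3 added settings, and no named gene or list reversed. With only the compared libraries, SCO against CAP7 with TNF gave 738 in place of 1322 genes and CAP7 against ROSI with TNF 791 in place of 1237, with fewer libraries to estimate the spread. Leaving out 1 library moved SCO against CAP7 most, to between 522 (without SCO replicate 1) and 743 of 872 without TNF, and to between 689 (without TNF plus SCO replicate 3) and 1527 with TNF, with 723 without TNF plus CAP7 replicate 1. The cause was not tested.

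Over the libraries left out in turn, calls ranged from 7331 to 7550 for TNF, 2198 to 2535 for SCO and 2530 to 2910 for SCO with TNF. Genes shared by SCO and ROSI ranged from 1960 to 2351 without TNF and 2190 to 2586 with TNF, and TNF-called genes moved back by SCO from 1943 to 2291. The ROSI lists kept medians of 0.22 to 0.25 and -0.19 to -0.16 in SCO with TNF. Over 7 comparisons 111 list tests passed with camera, 80 with an estimated correlation and 127 with fry.

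The labels do not say that a replicate number marks a shared day, and the same number was taken as a name only: correlations of same-numbered libraries ran from -0.106 to 0.157 (median 0.011), 3 of 112 were over 0.1, and 16 of 32 libraries were closest to their own number. With the numbers shuffled within groups 7.97 were on average (permutation p = 0.0167), a hint from the data that same-numbered libraries share a little. The replicate block gave 7856 calls for TNF, 2834 for SCO and 3137 for SCO with TNF, with 2440 and 2683 genes shared with ROSI, 2379 moved back and list medians of 0.23 and -0.18. It moved no count past 1.5 times, changed no call of a named gene, and changed 2 list results, 1 gained and 1 lost.

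With library size alone the median of all genes moved by -0.14 for ROSI and -0.16 for ROSI with TNF, and by -0.11 and -0.10 for CAP7. The share of calls that were higher then went from 53.4% to 35.3% for SCO, 50.3% to 28.8% for CAP7 and 49.2% to 27.8% for ROSI, and with TNF from 62% to 44.2%, 55.8% to 36.9% and 54.6% to 31.7%. For pairs of compounds it went from 50.2% to 72% (SCO against ROSI), 49.8% to 71.6% (SCO against CAP7) and 46.2% to 57% (CAP7 against ROSI), and with TNF from 39.9% to 67.8%, 45.1% to 61% and 40.6% to 61.9%. The balance of higher and lower calls therefore depends on the composition factor in these 12 comparisons, while TNF alone (49.3% and 50.9%) and the interactions (75.7% and 75.6%, 63.4% and 65.2%, 69.2% and 66.1% for SCO, CAP7 and ROSI) moved by less. Of named genes, Adipoq then passed with SCO (-0.18, adjusted p = 0.0466 in edgeR). Ccl2 in SCO against ROSI without TNF missed the threshold in limma-voom (0.77, adjusted p = 0.0603), and Pck1 in SCO against CAP7 without TNF passed with no filter on low counts (-0.359, adjusted p = 0.000268) and with only the compared libraries (-0.353, adjusted p = 0.00412). With all libraries thinned to the lowest total, SCO with TNF gave 2836 in place of 3074 genes. At the depths and group sizes of this series, simulated changes of 1.5-fold were recovered in 70% of cases for SCO with TNF and 46% for the interaction, and how far depth limits this was not simulated.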

Other observations

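Without TNF the interferon response genes varied between replicate libraries of the same treatment. The mean log2 CPM of the list ran from 3.04 to 4.36 over 4 vehicle libraries, from 2.31 to 4.09 with CAP7, from 2.59 to 3.57 with SCO and from 2.63 to 4.33 with ROSI, while that of NF-κB genes ran from 2.47 to 2.52 with vehicle, from 2.02 to 2.33 with CAP7, from 2.12 to 2.27 with SCO and from 1.955 to 2.13 with ROSI. The compounds were not shown to change interferon genes as a set without TNF, with an estimated correlation (adjusted p = 0.502 for SCO, 0.497 for CAP7 and 0.782 for ROSI in camera).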
